A study of Mus musculus with 6 samples.

How the data were processed

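The arrays measured total RNA from 6 mouse T-ALL samples, 3 WT (ethanol) and 3 KO (4-hydroxy-tamoxifen). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, 10 ng of RNA per sample went into whole-transcript amplification and biotin labelling, and the leukemias were grown in recipient mice, where tamoxifen was given at 5 mg per mouse, or treated in culture for 36 hours. Amplification from so little RNA can distort the relative signal of transcripts, and a sample that amplified differently shifts many probes at once.

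The deposited table of the whole series held, for each array and probe, a linear intensity and a detection p-value, per the file headers. The intensities were neither background-subtracted nor normalized between arrays, as seen from values of at least 101.9 and from medians that differed between arrays (133.8 to 153.5). The scanner and summary software are not given in the sources used here. A second deposited table held the authors' processed values on the log2 scale. Each of its columns had the same order of probes as that array's intensities, with medians of 7.20 on every array, and its values equalled the quantile-normalized log2 intensities within 0.00443. Its scale and direction were settled by this comparison, and it was not centred. No column of other samples was present (0).

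The intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3. This fits a normal plus exponential model whose background moments come from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Quantile normalization makes the distribution of values equal on all arrays, so a shift of most genes in one direction could not be seen. Probe names came from the platform's annotation: 34885 of the 45281 probes had 1 gene symbol, 18 had several and 10378 had none here. Symbols were checked against a RefSeq table of the GRCm38.p6 assembly, in which 34807 probes were matched, and 0 symbols changed. No genome build is given in the sources used here for the arrays, so no coordinates are printed. A probe was kept when its detection p was under 0.05 on at least 3 arrays, which left 16287. For a gene with several such probes the one with the highest mean over all 6 arrays was used, and probes without a single symbol were kept as features of their own. This gave 8836 named genes and 2405 unnamed probes, 11241 features in all.

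KO was compared with WT by limma's linear model with empirical Bayes moderation (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 11241 features and no covariates. Log2 changes are KO minus WT. Where all 3 arrays of a group failed detection, the fold is given as "at least": the detected group's mean against the mean, over the arrays of the other group, of the higher of the lowest detected signal and the probe's own signal. This bound covers the detection limit only and not the spread between arrays. Such a gene passed the filter only through its detected group. Gene lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 20 lists with at least 4 tested genes, and again with an estimated correlation and with fry. The count "adjusted over the list alone" applies Benjamini-Hochberg to the members of 1 list. The 25 lists held 407 different genes, of which 373 had a named probe and 241 were tested. Several genes belong to more than 1 list, such as Bbc3, Il7r and Sesn1. Single values of 3 against 3 arrays were compared by a two-sided exact permutation test, whose smallest p is 0.1.

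The following were fixed before the data were examined: the groups, the test, the lists, the processing alternatives, and the rule for named genes. That rule takes Hes1, and the 12 largest rises and 12 largest falls past the threshold with non-overlapping groups, filled where fewer pass by the smallest unadjusted p and then described as not past the test. It adds up to 4 members of each list by smallest p, and Bbc3, Bcl2l11, Myc, Cebpa, Cyld, Cdkn1b and Nr3c1, and another gene that is not reported here. Slc16a3 and the markers of other cell types in the closing part that were not tested were named after their values were seen.

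The alternatives were no background correction, a normexp fit on the signals alone with offset 50, median scaling, cyclic loess, the authors' log2 values, no filter, detection p under 0.01 on all arrays, the mean of a gene's probes or each probe alone, a replicate block, array weights, a trended robust prior, thresholds of adjusted p under 0.1 or at least 1.5-fold, and leaving out each array in turn. The alternatives added after the data were seen are named in the closing part. The steps were tested on simulated data for the comparison of KO with WT, with 200 genes changed in each of 5 runs and a mean of 14186 simulated features tested per run. Among changed genes that were tested, 0.311% were recovered at a log2 change of 0.5, 48.8% at 1 and 87.6% at 2, and 6.07% of calls were false. A list of 12 genes shifted by -0.5 was called in 5 of 5 runs, and 0 of 95 unchanged lists were. The simulated genes varied independently of each other, so these runs cannot show how often correlated lists are called by mistake. On the real arrays the estimated correlation within a list ran from -0.0619 for p53 targets to 0.484 for glycolysis.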

Results

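Gene expression was measured in mouse T-cell acute lymphoblastic leukemia (T-ALL), a cancer of T-cell precursors. The leukemias were driven by an activated form of NOTCH1 and carried Hes1 alleles flanked by loxP sites together with a Cre recombinase that 4-hydroxy-tamoxifen switches on. Hes1 is a basic helix-loop-helix transcriptional repressor whose gene NOTCH1 signalling activates. RNA was read on Illumina mouse bead arrays from 3 samples given ethanol for 36 hours, in which Hes1 was left intact (WT), and from 3 samples given 4-hydroxy-tamoxifen for 36 hours to delete Hes1 (KO). The labels call the replicates biological but do not say whether they came from separate leukemias, mice or cultures, so the p-values measure the spread between these samples, part of which may be technical. The labels describe both treatment of cultured cells and tamoxifen given to recipient mice, and they do not settle which material each RNA came from.

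Each array held 45281 probes. The mean signal per probe was 713, 708 and 703 intensity units on WT replicates 1, 2 and 3, and 520, 630.5 and 687 on KO replicates 1, 2 and 3. The group means were 708 ± 5.29 for WT and 612 ± 85.2 for KO (SD, n = 3 each), with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows. The number of probes detected at p under 0.05 was 15807, 16372 and 16023 on the WT arrays and 16414, 16232 and 16685 on the KO arrays. Across the features tested, KO replicate 1 had the lowest mean correlation with the other arrays, 0.981, against 0.990 to 0.991 for the others. These correlations run across genes, which are not independent replicates. The number of arrays limits the precision of every value given here.

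The comparison of KO with WT asked which genes change when Hes1 is deleted from NOTCH1-driven leukemia cells. Only KO samples were given 4-hydroxy-tamoxifen, and no array had the drug with Hes1 intact. For every gene and list other than Hes1 itself, loss of Hes1 therefore cannot be told apart from an effect of the drug or of Cre activity. Hes1 itself fell from a normalised log2 intensity of 10.98 ± 0.16 in WT to 4.54 ± 0.11 in KO (SD, n = 3 each). It was detected on all 3 WT arrays and on 0 of the 3 KO arrays, so its level in KO was at least 53.5-fold lower. Beyond Hes1, 4 genes rose and 2 fell. Snai3, which encodes a Snail-family zinc finger repressor, rose 4.44-fold, the largest rise among genes past the test. Wnt6, a secreted Wnt ligand, rose 2.46-fold, the stress-inducible gene Gadd45g rose 2.48-fold, and Arhgap25 rose 2.07-fold. Alox5ap, the 5-lipoxygenase-activating protein needed for leukotriene synthesis, was 2.65-fold lower in KO, and Sertad4, a SERTA domain family member, was 2.05-fold lower.

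For Hes1 the fitted log2 change, KO minus WT, was -6.44 ± 0.13 (SE) with a limma adjusted p of 1.0e-06. The single Hes1 probe tested was ILMN_1247691, and whether it lies in the deleted part of the gene is not given in the sources used here. Snai3 (probe ILMN_1239726) changed by 2.15 ± 0.11 on the log2 scale, with an adjusted p of 0.000747. Gadd45g (ILMN_2903945) changed by 1.31 ± 0.14, with an adjusted p of 0.0475. Another Gadd45g probe gave 1.54. Wnt6 (ILMN_2423835) changed by 1.30 ± 0.13, with an adjusted p of 0.0326. Of the other Wnt6 probes one gave 1.34 and the other 0.13, so the probes of this gene disagree. Arhgap25 (ILMN_3155245) changed by 1.05 ± 0.12 and lay at the edge of the threshold, with an adjusted p of 0.04996. Alox5ap (ILMN_2863837) changed by -1.41 ± 0.11, with an adjusted p of 0.00914, and its other probe gave -1.36. Sertad4 (ILMN_1229745) changed by -1.04 ± 0.10, with an adjusted p of 0.0326. In each of these 7 genes all 3 KO values lay on one side of all 3 WT values.

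**Figure D1:**
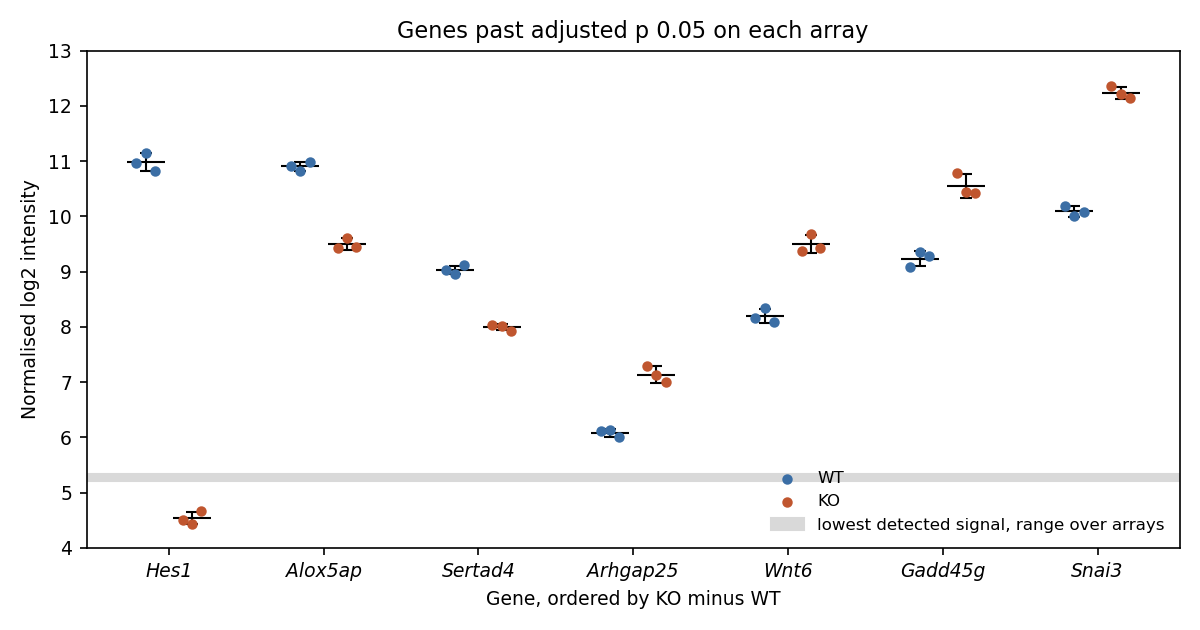
Normalised log2 intensity (vertical axis) of the 7 genes past adjusted p 0.05, for each of the 3 WT (blue) and 3 KO (orange) arrays, with black lines for the mean and SD of each group and a grey band for the lowest detected signal over the arrays. The 3 Hes1 values in KO lie below the band, around a mean of 4.54, and Snai3 rises from 10.09 to 12.24.

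In all, 7 of 8836 named genes passed an adjusted p of 0.05 in limma, 4 higher and 3 lower in KO, and 776 had an unadjusted p under 0.05, 401 higher and 375 lower. None of the 2405 unnamed probes tested passed (0), and 266 of them had an unadjusted p under 0.05. The KO and WT values did not overlap in 1443 named genes, or 16.3%, where chance gives 10%. With median scaling in place of quantile normalisation, 20 genes passed, 6 higher and 14 lower, and the median of all features moved to -0.17 on the log2 scale. Only Hes1 and Snai3 passed in all 6 fits that left out 1 array. The number of genes was 2 without WT replicate 1, 2 without WT replicate 2, 2 without WT replicate 3, 9 without KO replicate 1, 3 without KO replicate 2 and 2 without KO replicate 3, and over other settings it ran from 2 with a replicate block to 89 with array weights.

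The next genes by p were not past the test. Bbc3, which encodes the pro-apoptotic protein PUMA, measured 0.86 ± 0.12 higher in KO on the log2 scale (adjusted p 0.0843 in limma). Its other probe measured 0.05. Over 11 alternative settings the adjusted p of Bbc3 ran from 0.0165 to 0.365 and was under 0.05 in 6. Other genes with higher values in KO were Dennd3 (1.20), Ace, the angiotensin-converting enzyme (1.15), Plxdc1 (0.78), Rgma (0.74), Tnfaip2 (0.73) and the adhesion gene Cdh1 (0.70), whose other probe measured -0.29. The other Ace probes measured 1.01 and 0.32. Lrrk1 was not detected on the WT arrays and was at least 1.254-fold higher in KO. Genes with lower values in KO were Ankrd37 (-1.59), 4930486L24Rik (-1.25), Greb1 (-1.12), the adenylate kinase Ak4 (-1.12), the collagen prolyl hydroxylase P4ha1 (-0.97), Trib3 (-0.94) and Eif4ebp1, a brake on cap-dependent translation (-0.79). A second P4ha1 probe measured -0.49. Olfr1443 and Nutm2 were not detected on the KO arrays and were at least 1.51-fold and at least 1.21-fold lower. The adjusted p of these genes lay between 0.0536 for Olfr1443 and 0.136 for Ak4.

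Genes fixed in advance were also read one by one. Cyld, Cdkn1b, Cebpa and Nr3c1 were on the list of genes described as repressed by HES1, while Bcl2l11 and Myc were not. The pro-apoptotic gene Bcl2l11 measured -0.11 ± 0.11 (SE, log2), Myc 0.08 ± 0.15, the deubiquitinase gene Cyld 0.11 ± 0.13 and the cell cycle inhibitor gene Cdkn1b -0.39 ± 0.28, with adjusted p in limma between 0.689 and 0.882. Single arrays moved these values: over the fits without 1 array Cdkn1b ran from -0.61 to -0.14, Bcl2l11 from -0.19 to -0.04, Cyld from 0.01 to 0.19 and Myc from -0.03 to 0.19. With median scaling Cyld measured -0.11 and Myc -0.12. The other Bcl2l11 probes measured 0.0669 and 0.0024, and the other Cyld probe 0.0044. Cebpa was detected on 0 arrays and Nr3c1 on 2, so neither was tested. The list of genes described as repressed by HES1 had 4 tested members, 3 higher and 1 lower, and 1 rose when adjusted over the list alone, Bbc3. Bbc3 was placed on this list with knowledge of the study, so its count there is not independent evidence. The list did not pass camera (adjusted p 0.1497).

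The glycolysis list passed camera as lower in KO with a preset correlation of 0.01 (adjusted p 1.7e-08), but not with an estimated correlation (0.254) or fry (0.0514). Of 12 glycolysis genes tested, 11 had lower values, and 7 fell when adjusted over the list alone. The examples were Slc2a1, the glucose transporter GLUT1 (-1.04 ± 0.19, SE, log2), Pfkp, which makes a phosphofructokinase (-0.78 ± 0.15), Pgk1, phosphoglycerate kinase (-0.57 ± 0.11), and Pgam1, phosphoglycerate mutase (-0.52 ± 0.13). A second Pgam1 probe measured -0.06. The lactate transporter gene Slc16a3 was the 1 member with a higher value, 0.04. The median change was -0.47. The number that fell over the list alone moved with single arrays: it was 3 without KO replicate 3, 4 without WT replicate 1, 4 without KO replicate 2, 5 without WT replicate 3, 7 without WT replicate 2 and 9 without KO replicate 1, the dimmest array.

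The hypoxia response list passed camera as lower in KO with the preset correlation (adjusted p 5.6e-08) and with fry (0.0393), but not with an estimated correlation (0.254). All 11 hypoxia response genes tested had lower values, and 6 fell when adjusted over the list alone. They included Ankrd37 (-1.59 ± 0.25, SE, log2), P4ha1 (-0.97 ± 0.14), the mitophagy receptor gene Bnip3l (-0.43 ± 0.12) and Egln1, which encodes an oxygen-sensing prolyl hydroxylase (-0.55 ± 0.16). The median change was -0.40. The number that fell over the list alone was 2 without WT replicate 1, 2 without WT replicate 2, 2 without KO replicate 3, 3 without KO replicate 2, 5 without WT replicate 3 and 7 without KO replicate 1. Without WT replicate 1, KO replicate 1 or KO replicate 3, 10 of 11 had lower values.

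**Figure D2:**
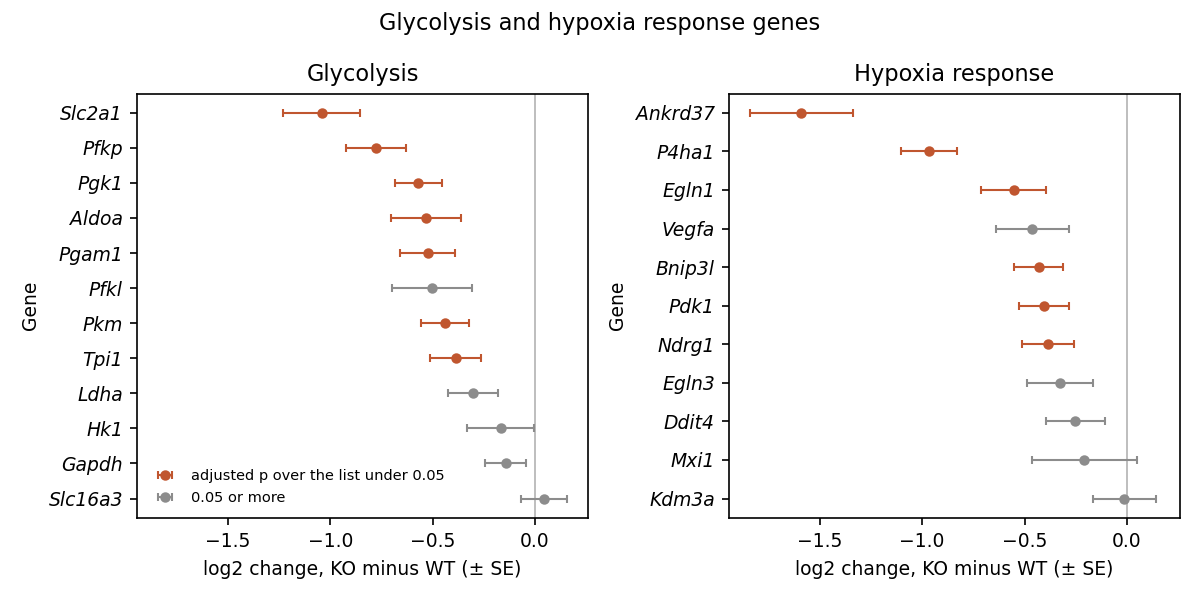
Log2 change, KO minus WT, with its SE (horizontal axis) for each tested gene of the glycolysis list (left) and the hypoxia response list (right), in orange where the p adjusted over the list alone is under 0.05 and in grey otherwise. The 7 and 6 orange genes all lie below 0, with Slc2a1 at -1.04 and Ankrd37 at -1.59.

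Of 14 genes of the unfolded protein and amino acid response, 12 had lower values in KO and 3 fell when adjusted over the list alone. These were Trib3, a pseudokinase gene induced by ATF4 (-0.94 ± 0.14, SE, log2), Asns, asparagine synthetase (-0.62 ± 0.11), and Ddit3, which encodes the stress factor CHOP (-0.43 ± 0.12). The chaperone cofactor gene Sdf2l1 measured -0.41 ± 0.17. The median change was -0.22, with an adjusted p of 0.000177 in camera, 0.254 with an estimated correlation and 0.0393 with fry. The median change was -0.12 without KO replicate 1 and -0.12 with array weights. Over the list alone 3 genes fell without KO replicate 1 and 2 without any other single array.

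The S-phase list passed camera as lower in KO with the preset correlation (adjusted p 0.0170), but not with an estimated correlation (0.254) or fry (0.0713), nor without WT replicate 1 (0.0650) or KO replicate 2 (0.0525). It passed in 10 of 12 alternatives that kept all arrays. Of 18 genes tested, 13 had lower values, 0 fell when adjusted over the list alone in limma, and 3 had an unadjusted p under 0.05. The replication gene Gins2 measured -0.46 ± 0.14 (SE, log2), Cdc6 -0.34 ± 0.14, Ccne1, cyclin E1, -0.30 ± 0.11, and Pcna, the replication clamp, -0.50 ± 0.24. A second Cdc6 probe measured -0.10. Over the fits without 1 array Pcna ran from -0.67 to -0.23 and Cdc6 from -0.45 to -0.23. The median was -0.15. Of 12 G2/M genes tested, 7 had lower values, 0 passed over the list alone and 1 had an unadjusted p under 0.05, Cdk1 (-0.38 ± 0.13). The G2/M list did not pass camera (adjusted p 0.447).

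Cholesterol synthesis was the one list that passed as higher in KO in camera with the preset correlation, and it passed neither with an estimated correlation nor with fry. Of 17 genes tested, 12 had higher values, and 1 rose when adjusted over the list alone, Mvd, mevalonate diphosphate decarboxylase (0.69 ± 0.12, SE, log2), while 0 rose with a replicate block or with median scaling. Sqle, squalene epoxidase, measured 0.33 ± 0.10, the regulator gene Srebf2 0.38 ± 0.14, and Sc5d, sterol C5 desaturase, went the other way at -0.33 ± 0.13. Srebf2 ran from 0.25 to 0.45 over the fits without 1 array. Second probes of Sqle and Srebf2 measured 0.16 and 0.13. The median was 0.17, with an adjusted p of 0.0282 in camera, 0.406 with an estimated correlation and 0.299 with fry. It was 0.11 without KO replicate 3 and 0.26 without KO replicate 1. With median scaling the list's median was -0.07, which lay 0.11 above that of all features, and the camera adjusted p was 0.0845. The camera adjusted p was 0.0621 with a replicate block, 0.127 without WT replicate 2, 0.358 without KO replicate 2, 0.137 without KO replicate 3 and 4.8e-05 without KO replicate 1, when 2 genes rose over the list alone.

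**Figure D3:**
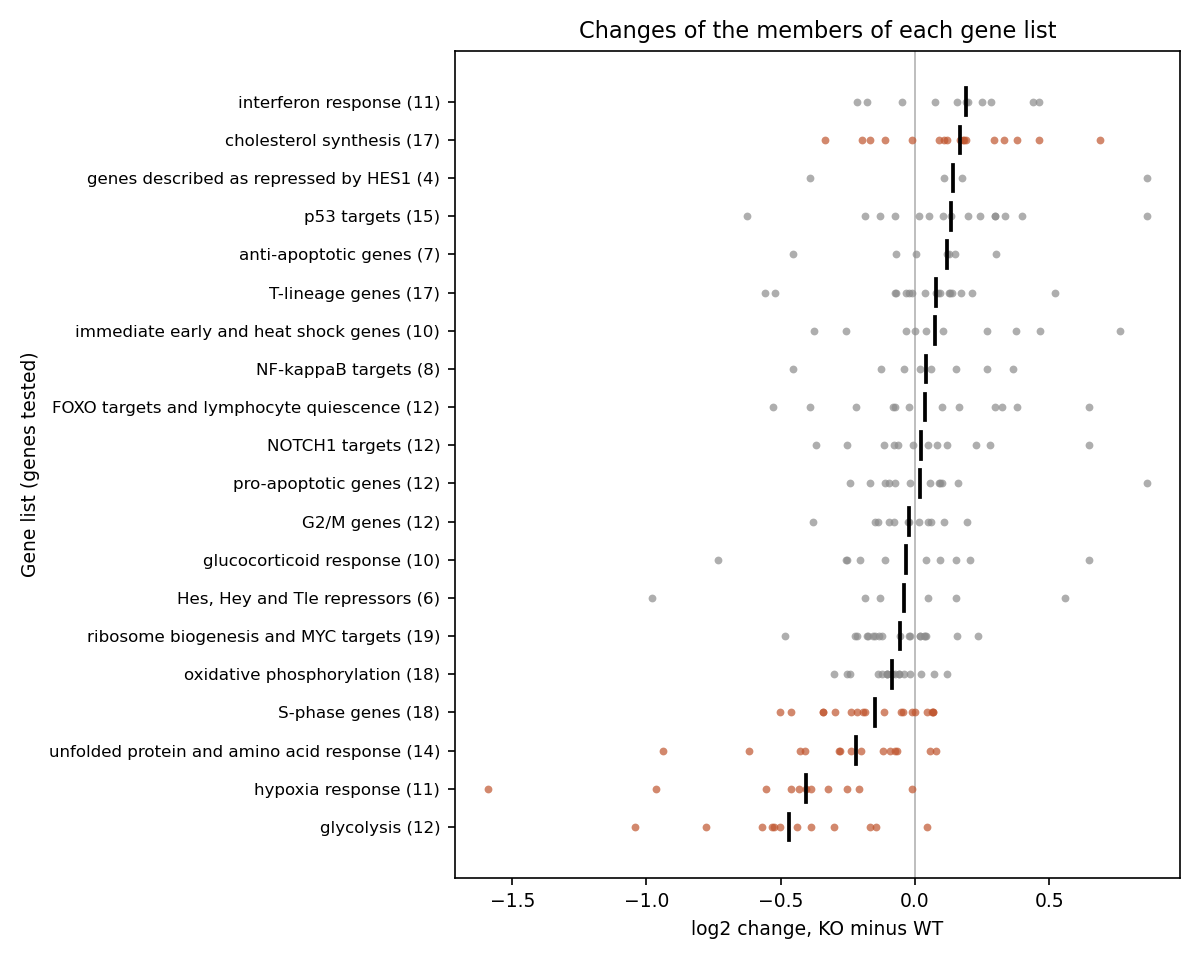
Log2 change, KO minus WT (horizontal axis), of every tested member of the 20 gene lists with at least 4 tested genes (number tested in parentheses), with a black bar for each list's median and orange points for the 5 lists past adjusted p 0.05 in camera. Glycolysis and hypoxia response have the lowest medians, -0.47 and -0.40, and interferon response has the highest, 0.19.

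In all, 5 of 20 lists passed camera, 4 lower and 1 higher in KO. With an estimated correlation 0 lists passed and 3 had an unadjusted p under 0.05. With fry, which tests whether a list's genes move on balance one way without comparing them with other genes, 3 passed, and 13 passed its test of change in either direction. No list member passed the limma test over all genes (0 of 241), and 54 had an unadjusted p under 0.05. Without KO replicate 2, 3 lists passed, and without KO replicate 1, 7 passed.

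Lists of NOTCH1, apoptosis and p53 genes did not pass camera with the preset correlation. Of 12 NOTCH1 targets, 6 had higher and 6 lower values, and 1 rose when adjusted over the list alone, Il7r, the interleukin-7 receptor (0.65 ± 0.10, SE, log2), while with median scaling 0 rose. Nrarp, a feedback inhibitor of NOTCH signalling, measured -0.37 ± 0.10. Of 6 other Hes, Hey and Tle repressor genes, 1 rose over the list alone, Tle6 (0.56 ± 0.14), and 1 fell, the basic helix-loop-helix repressor gene Bhlhe40 (-0.98 ± 0.23). Of this list 0 genes rose without WT replicate 1 or WT replicate 3 or with median scaling, and 0 fell without WT replicate 1. Of 12 pro-apoptotic genes, 6 had higher values and 1 rose over the list alone, Bbc3, while Bad measured -0.17 ± 0.12. Of 7 anti-apoptotic genes, 5 had higher values, 0 passed over the list alone in limma and 1 had an unadjusted p under 0.05, Bcl2 (0.30 ± 0.11). The other Bcl2 probes ran from -0.03 to 0.53. Of 15 p53 targets, 11 had higher values and 1 rose over the list alone, again Bbc3, with Zmat3 at 0.34 ± 0.12 and Sesn1 at 0.30 ± 0.11. The other Sesn1 probes measured -0.19 and 0.18. With the mean of all probes of a gene, 0 pro-apoptotic and 0 p53 genes rose over the list alone. The p53 list had an adjusted p of 0.0570 in camera, 0.0179 with fry, 0.0326 in camera without KO replicate 1 and 0.254 with an estimated correlation. It was under 0.05 in 7 of 12 alternatives that kept all arrays, fry among them. The camera adjusted p was 0.777 for the NOTCH1 targets, 0.712 for the Hes, Hey and Tle genes, 0.677 for the pro-apoptotic and 0.447 for the anti-apoptotic genes.

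Among signalling and stress lists, 3 of 10 immediate early and heat shock genes rose when adjusted over the list alone. These were the transcription factor genes Egr1 (0.76 ± 0.15, SE, log2), Jun (0.47 ± 0.14) and Egr2, which was not detected on the WT arrays and was at least 1.13-fold higher in KO. Of this list 0 genes rose without WT replicate 2 or with median scaling, 2 without WT replicate 3, and 1 without any other single array. Of 10 glucocorticoid response genes, 1 rose over the list alone, Il7r, and 1 fell, the kinase gene Sgk1 (-0.73 ± 0.12). Of 12 FOXO targets and lymphocyte quiescence genes, 1 rose over the list alone, Il7r again, and 1 fell, the repressor gene Bcl6 (-0.53 ± 0.13). With median scaling 0 genes of either list rose. Without any single array other than WT replicate 2, and with a replicate block, 0 genes of the FOXO list fell. Of 11 interferon response genes, 8 had higher values, with Irf7 at 0.46 ± 0.19 and Isg15 at 0.25 ± 0.11, and of 8 NF-kappaB targets 5 had higher values, with Icam1 at 0.36 ± 0.12 and Nfkbie at 0.27 ± 0.11. In both lists 0 genes passed over the list alone in limma, with 1 interferon and 2 NF-kappaB genes at an unadjusted p under 0.05. Irf7 ran from 0.26 to 0.62 over the fits without 1 array. The camera adjusted p was 0.144 for the immediate early, 0.563 for the glucocorticoid, 0.359 for the FOXO, 0.1004 for the interferon and 0.447 for the NF-kappaB list, and for the interferon list it was 0.00930 without KO replicate 1, 0.0121 with array weights and 0.0149 with no filter on dim probes.

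Growth lists did not pass camera with the preset correlation. Of 19 genes of ribosome biogenesis and MYC targets, 12 had lower values, with Nolc1 at -0.48 ± 0.16 (SE, log2) and Mrto4 at -0.22 ± 0.11. Of 18 oxidative phosphorylation genes, 15 had lower values, with Cox6c at -0.25 ± 0.14 and Cycs, cytochrome c, at -0.24 ± 0.16. Over the fits without 1 array Cox6c ran from -0.33 to -0.14 and Cycs from -0.33 to -0.11. The other Cycs probes measured -0.0017 and -0.0215. In both lists 0 genes passed over the list alone in limma, with 1 ribosome gene and 0 oxidative phosphorylation genes at an unadjusted p under 0.05, and the camera adjusted p was 0.144 for each. Without KO replicate 1, 1 gene of the ribosome list fell over the list alone, and 8 of the 18 oxidative phosphorylation genes had lower values. With no filter on dim probes the oxidative phosphorylation list passed as lower (adjusted p 0.0458).

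T-lineage genes were well expressed in both groups. Of 17 tested, 10 had higher and 7 lower values in KO, and 1 rose when adjusted over the list alone, the adhesion gene Cd2 (0.52 ± 0.11, SE, log2). Over the list alone 0 genes rose without WT replicate 1, 2 or 3, without KO replicate 2, with a replicate block or with median scaling, and 1 fell without KO replicate 3. The co-stimulatory receptor gene Cd28 measured -0.56 ± 0.17. The list did not pass camera (adjusted p 0.447). Few markers of other cell types could be tested at all. Of 20 myeloid genes with a named probe 2 were tested, Cebpb at -0.31 ± 0.13 and Fcer1g at 0.12 ± 0.10, or -0.10 with median scaling. Of 9 B-lineage genes 2 were tested, Vpreb1 at -0.27 ± 0.23 and Ebf1 at 0.22 ± 0.13. Ebf1 was not detected in WT and was at least 1.10-fold higher in KO against the detection limit, but its unadjusted p was 0.139 in limma. Of 7 erythroid genes 1 was tested, Klf1 at -0.53 ± 0.39. Of these 5 genes 0 passed over their lists in limma and 1, Cebpb, had an unadjusted p under 0.05. Single arrays moved 2 of them: over the fits without 1 array Klf1 ran from -0.95 to -0.25 and Vpreb1 from -0.51 to -0.06. Of 12 stromal and endothelial genes, 3 were tested and 1 rose over the list alone, the adhesion gene Pecam1 (0.53 ± 0.16). Of 10 NK and cytotoxic genes, 1 was tested, Prf1, the pore-forming protein perforin, which measured 1.24 ± 0.50 (unadjusted p 0.0406 in limma) with KO and WT values that overlapped and a change of 0.73 without KO replicate 1.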

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

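The unnamed-probe alternative, array weights in camera, and counts over a list alone under any alternative were added after seeing the data. Hes1 (log2 change -6.53 to -4.002 over 10 alternatives) and Snai3 (1.94 to 2.17 over 11) kept their direction and stayed past the threshold, except that Hes1, not detected in KO, is left out by construction where detection on all arrays is required. Where the cause of a change is not named, the cause was not tested. The slide block was not run because no slide is given in the sources used here. Dim probes limit the results, since a level under the detection limit gives only a bound.

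The 7 genes became 31 without background correction, 26 with normexp on signals alone, 20 with median scaling, 31 with the authors' values, 15 with detection on all arrays, 89 with array weights, 40 with a trended robust prior and 19 at adjusted p under 0.1. Without 1 array, with fewer samples, the count ran from 2 to 9. With the replicate block it was 2. The deviations of same-numbered arrays correlated at -0.0977, -0.272 and 0.1502, and 1 of the 6 arrays correlated best with its own number. These values give no sign that the numbers pair the samples. So few arrays per group cannot exclude pairing, and the labels do not say what a shared number means.

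The 5 lists became 8 with no filter (p53, interferon and oxidative phosphorylation gained), 7 with array weights (p53 and interferon gained), 6 with no background correction, normexp on signals alone, the authors' values or detection on all arrays (p53 gained in each), 4 with median scaling or the replicate block (cholesterol lost in both), 0 with an estimated correlation, 3 with fry, 13 with fry in either direction and 3 to 7 without 1 array. The estimated correlation gave an adjusted p of 0.254 for glycolysis, hypoxia response, unfolded protein and S-phase genes and 0.406 for cholesterol synthesis, and fry gave 0.0514 for glycolysis, 0.0713 for S-phase and 0.299 for cholesterol. Cholesterol synthesis had 0.0845 with median scaling and 0.0621 with the replicate block. The block changed no other list call. Without 1 array the adjusted p was 1.0e-10 to 9.7e-06 for glycolysis, 9.0e-10 to 2.2e-05 for hypoxia, 0.000123 to 0.00182 for unfolded protein, 0.0151 to 0.0650 for S-phase and 4.8e-05 to 0.358 for cholesterol.

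By the fitted change of a gene or camera's direction of a list, directions turned only in results not past the threshold. The median of the cholesterol list did turn with median scaling, to -0.07, with 5 genes higher and 12 lower. Camera, which compares a list with the other genes, still gave it as higher (adjusted p 0.0845). With median scaling Cyld was -0.11, Fcer1g -0.10 and Myc -0.12, and the NOTCH1 (adjusted p 0.789) and T-lineage (0.747) lists turned lower. With the mean of all probes the NOTCH1 (0.823) and T-lineage (0.979) lists turned lower, with array weights the NOTCH1 (0.828) and pro-apoptotic (0.916) lists did, and with detection on all arrays the Hes, Hey and Tle list turned higher (0.971). Without 1 array, Myc ran from -0.0259 to 0.194, and some fits turned the Hes, Hey and Tle (0.452 to 0.911), NOTCH1 (0.558 to 0.840) and pro-apoptotic (0.589 to 0.990) lists.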

Other observations

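The tests of the count of genes, of a single array, of drug and Cre exposure, of the abundant transcripts of other cell types, of the spread of markers over the arrays, and of rises against falls were chosen after the results were seen. Tests of the count of lists, of matched random gene sets, of signal and of markers on 1 array alone were written before being run. Except for the count of lists, they concern patterns first seen in these same data. These patterns were the lower glycolysis and hypoxia genes and the distance of KO replicate 1 from the other arrays.

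The nearest tested genes on each side of Hes1 on its chromosome did not pass the test. These were 10 genes, at positions -69 to 33 counted in genes from Hes1 along the GRCm38.p6 assembly. They were taken in equal number from each side, so they are not strictly the 10 nearest. Of these genes 0 passed in limma and 3 had an unadjusted p under 0.05, all with lower values. Opa1, a mitochondrial fusion gene at position -9, measured -0.60 ± 0.19 (SE, log2) with an adjusted p of 0.422. The other lower genes lay much farther away. Bcl6, at position -61, measured -0.53 ± 0.13 with an adjusted p of 0.289. Rtp1, at position -69, measured -0.53 ± 0.19 with an adjusted p of 0.456. Opa1 and Rtp1 were named after their values were seen. Perforin (Prf1) differed widely between arrays of the same group: its normalised log2 intensity was 8.40, 9.82 and 9.04 on the WT arrays and 11.35, 9.52 and 10.12 on the KO arrays.

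Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 7 genes, and the highest of the others gave 0. For the lists 1 split, again the real one, gave as many as 5, and the highest of the others gave 3. With 10 splits the share can never be under 0.1, so they are too few to decide whether chance is excluded.

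The glycolysis and hypoxia lists passed camera as lower in KO with the preset correlation, and neither passed with an estimated correlation (adjusted p 0.254 for each). The highest camera adjusted p of both lists over the 6 fits without 1 array was 2.2e-05 with the preset correlation. That p is weak evidence, since the estimated correlation was 0.484 for glycolysis and 0.224 for hypoxia. A single array is argued against as the whole cause by the list means, taken as deviations from the mean of all 6 arrays. For glycolysis they were 0.30, 0.19 and 0.18 on the WT arrays and -0.08, -0.19 and -0.40 on the KO arrays. For hypoxia they were 0.31, 0.33 and 0.13 on WT and -0.23, -0.15 and -0.38 on KO. A shift of bright probes is argued against as well: the 23 genes of both lists had a median of -0.43, and 10000 random sets matched on mean level one of -0.004. Of these sets 0% went as low, with -0.17 the lowest. The lists were picked for their falls in these same data, so this share does not measure how unusual they are. Exposure to 4-hydroxy-tamoxifen or Cre activity cannot be told apart from loss of Hes1, because 0 arrays had the drug with Hes1 intact. The same limit holds for every other gene and list that differed between KO and WT. No biological explanation was tested.

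KO replicate 1 stood apart from the other arrays. Its median difference from KO replicates 2 and 3 was 0.26 on the log2 scale, against 0.13 between those arrays and 0.14 to 0.18 between WT arrays. Lower signal alone is argued against, since the ratio of these differences was 2.15 in the brightest of 3 equal bins of genes and 1.47 in the dimmest. Of 8 abundant transcripts of myeloid, B, erythroid and fibroblast cells (Lyz2, S100a8, S100a9, Mpo, Tyrobp, Cd74, Hba-a1 and Col1a1), 0 were detected on KO replicate 1 at p under 0.05. Every other array also detected 0, so no array shows that these probes can detect their transcripts. Erythroid cells rest on Hba-a1 alone, fibroblasts on Col1a1 alone and B cells on Cd74, which macrophages share. These values therefore do not exclude such cells. For myeloid cells, 4 of 20 myeloid markers were detected on KO replicate 1 at p under 0.01 and 2 on every other array. The added ones were Elane and Ctss, close to the detection limit, with 161.7 and 157.5 intensity units against 155.6 to 169 and 143.5 to 169.3 on the others. These intensities were not background-corrected, and the median of KO replicate 1 was lower, 133.8 against 146.3 to 153.5. Their overlap therefore does not show equal levels. Elane and Ctss were also the 2 of 58 marker genes of all types detected on this array alone, against at most 1 on any other (exact binomial p 0.0741, one-sided, against an even spread over the 6 arrays). Both are myeloid, so they give no sign of other cell types. Of the markers tested, Prf1, Pecam1 and Pdgfrb had their highest level on this array, and Cebpb, Klf1 and Kdr their lowest. Prf1 measured 11.35 there against at most 10.12 on the others, and Pecam1 10.20 against at most 9.89. Cells of any other type stay open. A difference in RNA quality or amplification stays open and was not tested, and no biological explanation was tested.

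Because HES1 is a repressor, one hypothesis is that its loss may mostly raise genes. Of the 18 genes other than Hes1 past an adjusted p of 0.1, 11 were higher and 7 lower in KO, with an exact binomial p of 0.481 (two-sided). The balance also depends on where normalisation places the median of all features, which median scaling moved to -0.17. These values do not tell an excess of rises from an even split.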
